A study of Mus musculus with 6 samples.

How the data were processed

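Skeletal muscle of mice lacking PRR14, a nuclear protein, was profiled 1 month after injection of an adeno-associated virus (AAV), a gene-delivery vector. The virus carried either MEF2C-GFP, the muscle transcription factor MEF2C with green fluorescent protein, or GFP alone. Each group had 3 libraries, all from the knockout. Per the labels, the tissue was skeletal muscle with no muscle named, and no wild-type or uninjected sample was part of the comparison analysed here. Per the labels' protocols, RNA came from frozen tissue, and 1 µg of total RNA entered an Oxford Nanopore PCR-cDNA library, in which template switching favours full-length cDNA and the cDNA is amplified by PCR before adapter ligation. Such reads carry no molecular identifiers in the protocol given, so that PCR duplicates cannot be removed, and intervals or floors cover counting error only.

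The deposited table holds read counts per gene, given as counts by the file header, and the CPM of the same libraries. The submitters' processing notes name minimap2, the genome build GRCm38 and DESeq2 1.6.3, without roles. The counting tool, the annotation, the use of strand and any read filter are not given in the sources used here, nor is whether viral MEF2C or GFP transcripts were in the reference. The deposited counts were whole numbers and were used as they stood. The deposited CPM, per the file headers scaled to the reads of the whole library, were divided into the counts only to recover the library totals behind them. The counts of the listed genes came to between 95.6% and 96.4% of those totals. The table held 22036 gene rows and 30 rows naming no gene, which were blank or broken annotation text, held 0 counts and were left out. No column of another sample was present. Gene coordinates, and the length and GC content of the longest transcript, came from GENCODE vM21 (GRCm38), where 22022 of the 22036 gene identifiers matched, including all 9229 tested genes. Gene symbols were those of the table.

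The listed counts per library were 3838894, 3824003 and 3814844 for MEF2C replicates 1, 2 and 3, and 3370833, 3471928 and 3900617 for GFP replicates 1, 2 and 3. A count of 0 allows up to 3 counts, which is between 0.769 and 0.890 CPM in these libraries. No pair of libraries from the same group agreed within sampling noise: the chi-square per degree of freedom over genes lay between 5.65 and 11.7. The labels do not say that the replicates are separate animals, and the p-values measure only the spread between these samples.

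Genes were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood test with robust dispersion (glmQLFit and glmQLFTest), after edgeR's filter by group and TMM normalisation, without a covariate. Calls had a Benjamini-Hochberg adjusted p under 0.05 with no fold minimum. Standard errors of log2 fold changes were taken from the F statistic, and normalised CPM were computed on the TMM-scaled listed totals. Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 36 lists that had at least 5 tested members. The median change of a list is the median over members of the difference in mean log2 CPM. The 41 lists and their 686 members, the tests and the named-gene rule were fixed before the data were examined. They covered fibre types, other muscle programmes, metabolism, stress responses and markers of other cell types. Mef2c was left out of the list tests. Members called are given over all genes tested and adjusted over the list alone.

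The text names Mef2c and Prr14, and the myosins Myh7, Myh2, Myh1 and Myh4 whatever their result. It names up to 10 called genes per direction with groups that do not overlap, a mean of at least 20 counts and a symbol that is not a predicted-gene name, filled to 5 by the smallest unadjusted p where fewer passed. For each list it names up to 4 called members, or up to 2 with the smallest p where none was called. Genes outside this rule are said to have been chosen after their values were seen. In the lists that were not called, the members the rule allows are named only in part. The result of 1 gene that the rule names is not reported here.

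Alternatives were DESeq2 1.42.0 size factors, library totals without TMM, library sizes without the 50 most abundant genes, no low-count filter, a stricter filter (at least 1 CPM in at least 3 libraries and a mean of at least 20 counts), the DESeq2 Wald test, limma-voom, non-robust dispersion, a block on the replicate number, a fold minimum, a prior count of 0.5, camera with an estimated correlation, fry, and leaving out each library in turn. Chosen after seeing the data were loess corrections per library on transcript length and on GC content (span 0.3), TMM on the totals behind the deposited CPM, and MEF2C replicate 3 alone against the 3 GFP libraries. The pseudocount alternative, meant for a table without counts, did not apply.

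The gene test was tested on simulated data drawn from these libraries' means and sizes for the comparison of MEF2C against GFP, with 9229 genes, 200 of them changed, in 5 datasets. It recovered 6.87% of genes changed 1.5-fold, 40% of those changed 2-fold and 89.4% of those changed 4-fold, and 8.32% of its calls were false. Genes were drawn independently, with dispersions fitted to these libraries. The 8.32% therefore does not cover variation between libraries that many genes share. The list test recovered 4 of 4 shifted lists and called 0 of 36 unshifted ones. These were random lists of 15 genes drawn independently of each other. The simulation therefore does not measure false calls in lists whose members vary together. In the libraries themselves the estimated inter-gene correlation was 0.77 for the slow-fibre list and 0.16 for the fast-fibre list.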

Results

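Counts per gene were analysed for 6 Nanopore PCR-cDNA libraries from skeletal muscle of PRR14-knockout mice, 3 labelled MEF2C (AAV carrying MEF2C-GFP) and 3 labelled GFP (AAV carrying GFP), collected 1 month after injection. PRR14 is a nuclear protein, and MEF2C is a transcription factor that drives muscle genes, including those of slow, oxidative fibres. The comparison asks which genes differ when MEF2C is supplied to knockout muscle, in a series on PRR14, mechanical signalling and myofibre identity. Listed counts ranged from 3370833 to 3900617 per library, and between 13001 and 13637 genes were detected in each. The 10 most abundant genes took 25.5% to 27.0% of the counts in the libraries labelled MEF2C and 29.2% to 32.9% in the GFP libraries.

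The gene carried by the virus was examined first, as a check on the labels. Mef2c (ENSMUSG00000005583, GRCm38 chromosome 13, 83504034 to 83667080, plus strand, protein-coding) stood at 234, 196 and 371 normalised CPM in MEF2C replicates 1, 2 and 3, and at 223, 261 and 236 in GFP replicates 1, 2 and 3. Only MEF2C replicate 3 lay above the GFP libraries, at 1.55 times their mean, while the mean of MEF2C replicates 1 and 2 was 0.895 times the GFP mean. The groups did not differ, with a log2 fold change of 0.15 ± 0.22 (SE) and an edgeR adjusted p of 0.993. The exact two-sided permutation test gave p = 0.9, where 3 libraries against 3 cannot go below 0.1. Without MEF2C replicate 3 the fold change turned to -0.16. The counts therefore do not tell MEF2C replicates 1 and 2 from the GFP libraries by this gene, and directions are given for the libraries labelled MEF2C. Prr14 (ENSMUSG00000030822, chromosome 7, 127459611 to 127476759) had 30, 23 and 20 counts in MEF2C replicates 1, 2 and 3 and 11, 12 and 15 in GFP replicates 1, 2 and 3, a log2 difference of 0.72 ± 0.32 (edgeR adjusted p = 0.856). With no wild-type library here, these counts do not check the knockout.

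**Figure D1:**
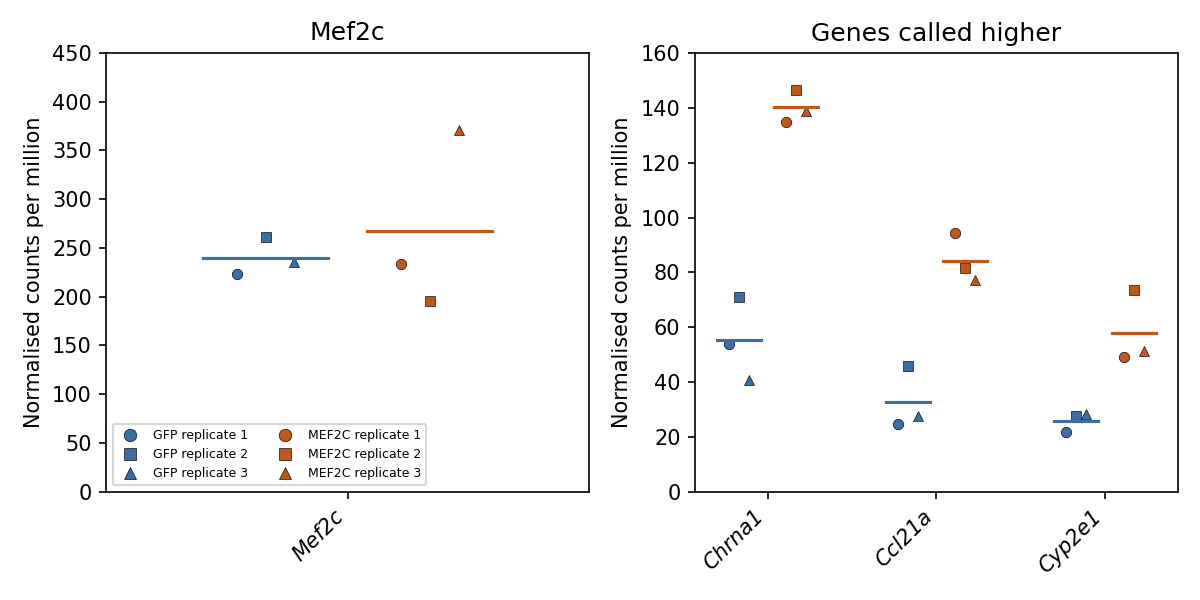
Normalised CPM (linear axes from 0) of Mef2c on the left and of the 3 genes called higher on the right, 1 point per library with its replicate as the symbol and the group mean as a bar, in libraries labelled GFP (blue) and MEF2C (orange). Mef2c is above the GFP libraries in MEF2C replicate 3, at 371, and not in replicates 1 and 2, whereas Chrna1, Ccl21a and Cyp2e1 are higher in all 3 MEF2C libraries.

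In the libraries labelled MEF2C, 3 genes were higher and 4 were lower among 9229 tested. The higher genes were Chrna1, the alpha subunit of the muscle acetylcholine receptor, Ccl21a, a chemokine of lymphatic vessels, and Cyp2e1, a cytochrome P450 enzyme. Of the 4 lower genes, 3 belong to the fast-fibre contractile and calcium-handling machinery, namely Pvalb (the calcium buffer parvalbumin), Mylpf (the fast regulatory light chain) and Myl1 (the fast essential light chain), and the other was Rtn4, a membrane-shaping protein of the endoplasmic reticulum. Chrna1 (ENSMUSG00000027107, chromosome 2, 73563215 to 73580338) rose from 55.3 ± 15.2 to 140 ± 5.95 CPM (SD, n = 3 per group), a log2 fold change of 1.35 ± 0.18 (edgeR adjusted p = 0.0162). Ccl21a (ENSMUSG00000094686, chromosome 4, 42772860 to 42773993) rose by 1.37 ± 0.21 (edgeR adjusted p = 0.0428) and Cyp2e1 (ENSMUSG00000025479, chromosome 7, 140763739 to 140774987) by 1.16 ± 0.19 (edgeR adjusted p = 0.0377). Pvalb (ENSMUSG00000005716, chromosome 15, 78191114 to 78206400) fell from 14688 ± 1644 to 8005 ± 650 CPM (SD, n = 3 per group), a log2 fold change of -0.88 ± 0.12 (edgeR adjusted p = 0.0162). Mylpf (ENSMUSG00000030672, chromosome 7, 127208890 to 127214298) changed by -0.79 ± 0.11 (edgeR adjusted p = 0.0189), Myl1 (ENSMUSG00000061816, chromosome 1, 66924295 to 66945404) by -0.78 ± 0.12 (adjusted p = 0.0342) and Rtn4 (ENSMUSG00000020458, chromosome 11, 29692947 to 29744331) by -0.69 ± 0.11 (adjusted p = 0.0428). The groups did not overlap for any of the 7 genes. Ccl21a shares nearly identical copies with predicted genes on the same chromosome, and its count is uncertain between them. The sum of Ccl21a, Gm21541 and Gm13304, chosen after their values were seen, was 142, 121 and 119 CPM in MEF2C replicates 1, 2 and 3 and at most 63.4 in the GFP libraries.

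The genes next in rank did not pass the test. Atp2a2, the slow-fibre calcium pump, had a log2 fold change of 1.21 ± 0.23 and Myh11, the smooth muscle myosin, 0.78 ± 0.16 (edgeR adjusted p = 0.12 and 0.126). Nrep stood at -0.79 ± 0.15 (adjusted p = 0.12). In all, 527 genes had an unadjusted p under 0.05, 310 of them higher, and 1023 genes (11.1%) had groups that did not overlap, where chance gives 10%. With non-robust dispersion edgeR called 0 genes, with 557 at an unadjusted p under 0.05. DESeq2 called 28 genes, 15 higher and 13 lower, including these 7, and limma-voom called 6.

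The 7 calls were sensitive to single libraries. Without GFP replicate 3 edgeR called 0 genes, with 386 at an unadjusted p under 0.05, and the adjusted p of the 7 lay between 0.140 and 0.443. Without MEF2C replicate 2 all 7 were lost as well (adjusted p between 0.117 and 0.220), and 1 other gene, Txnip, was called. Chrna1, Cyp2e1 and Pvalb passed without MEF2C replicate 1, Pvalb and Mylpf without GFP replicate 1, and Chrna1 and Ccl21a without GFP replicate 2, with 3, 2 and 2 genes called. Without MEF2C replicate 3 the count was 22, which held all of the 7 except Ccl21a (adjusted p = 0.0965).

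Genes of the slow-fibre sarcomere stood higher in the libraries labelled MEF2C. All 12 tested members had a positive log2 fold change, with a median of 2.16. Myh7, the slow myosin heavy chain (ENSMUSG00000053093, chromosome 14, 54970684 to 54994626), stood at 74.4, 68.0 and 20.1 CPM in MEF2C replicates 1, 2 and 3 and at 7.11, 0.319 and 3.71 in GFP replicates 1, 2 and 3, where the value in GFP replicate 2 is 1 read. Myl3, the slow essential light chain, stood at 588, 510 and 125 CPM against 17.5, 45.3 and 44.5. Over all genes 0 of the 12 were called by edgeR, while 8 had an unadjusted p under 0.05 and DESeq2 called 6. Adjusted over the list alone, 8 were higher, namely Myh7, Myl2, Myl3, Tnnt1, Tnni1, Tnnc1, Tpm3 and Atp2a2. The list was called higher (camera adjusted p = 3.69e-13; adjusted p = 0.676 with an estimated correlation). MEF2C replicate 3 had the lowest level of its group for each of these 8 genes. Without it Tnnt1, Tnni1, Tpm3, Atp2a2 and Casq2 passed over all genes, with edgeR adjusted p of 4.21e-05, 0.0189, 4.21e-05, 0.0189 and 0.0489. The median of the list was 1.08 for MEF2C replicate 3 alone against the GFP libraries, 1.35 without GFP replicate 2 and 1.15 with no low-count filter. Bglap, which encodes the bone protein osteocalcin, and Acp5, the acid phosphatase of osteoclasts, were also highest in MEF2C replicates 1 and 2: Bglap had 20, 17 and 1 counts in MEF2C replicates 1, 2 and 3 and 0 in each GFP library, and Acp5 stood at 24.4, 17.4 and 3.39 CPM in MEF2C replicates 1, 2 and 3 and at 7.98 or less in the GFP libraries. Apart from Myh7, Myl3 and Atp2a2, the genes named here were chosen after their values were seen.

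Fast-fibre genes were lower, by less. Of 16 tested members 14 had a negative log2 fold change and the median was -0.34. By edgeR, 3 members were lower over all genes and 7 adjusted over the list alone, namely Pvalb, Mylpf, Myl1, Casq1, Tnni2, Tnnc2 and Atp2a1, the last 4 chosen after their values were seen. Casq1, the fast calsequestrin that stores calcium, stood at 2985 ± 56.0 against 4360 ± 591 CPM (SD, n = 3 per group). The fast myosin heavy chains did not pass: Myh4 had a log2 fold change of -0.30 ± 0.15, Myh1 of -0.13 ± 0.31 and Myh2 of 0.91 ± 0.80 (edgeR adjusted p = 0.904, 0.993 and 0.993). Myh2 stood at 850 and 917 CPM in MEF2C replicates 1 and 2 and at 193 in replicate 3, against 318, 168 and 557 in GFP replicates 1, 2 and 3. The list was called lower (camera adjusted p = 2.09e-07; adjusted p = 0.676 with an estimated correlation), and its median was -0.21 with library totals alone.

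**Figure D2:**
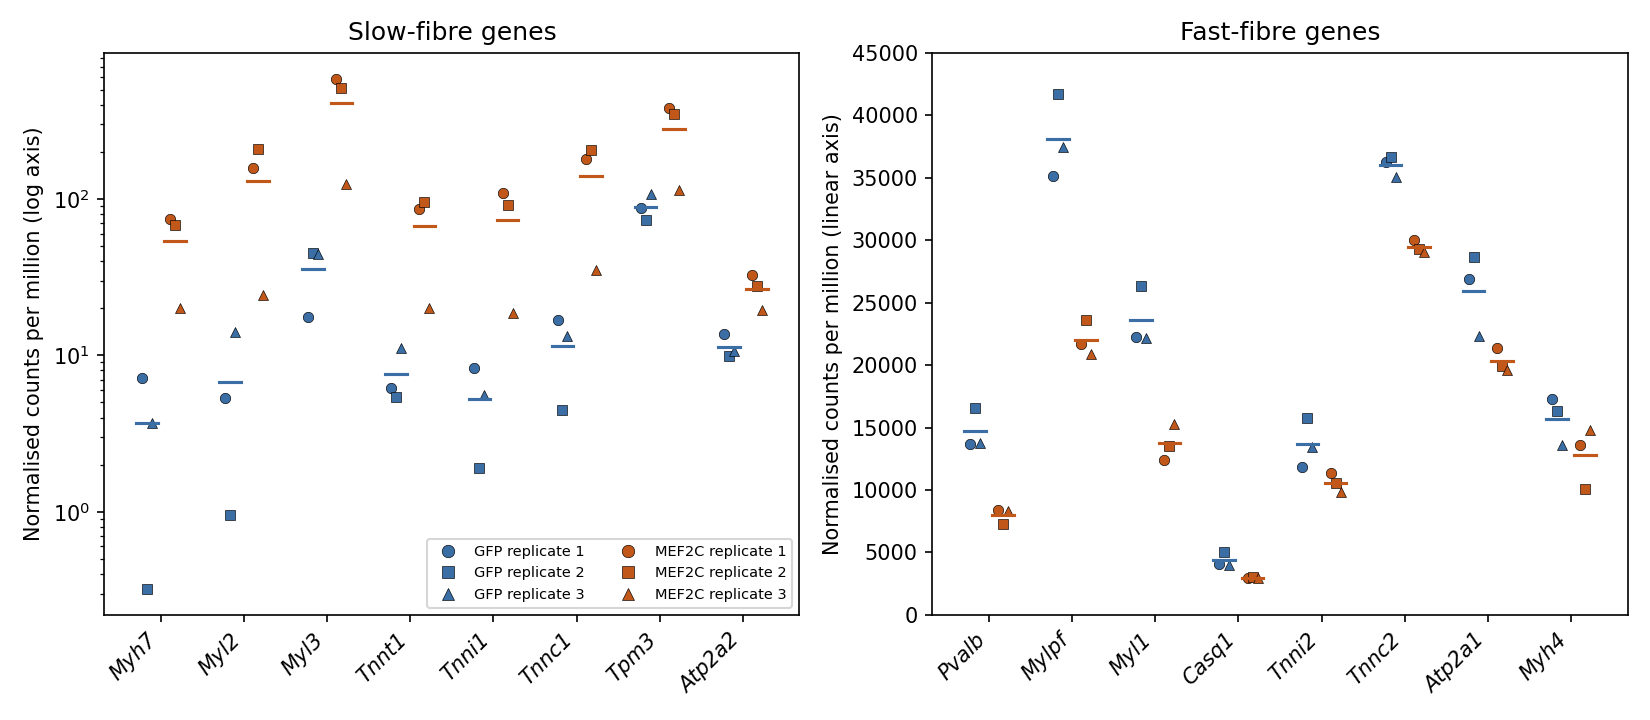
Normalised CPM per library of 8 slow-fibre genes (left, log axis) and 8 fast-fibre genes (right, linear axis from 0), with the replicate as the symbol and the group mean as a bar, in libraries labelled GFP (blue) and MEF2C (orange). For Myh7, MEF2C replicates 1 and 2 stand at 74.4 and 68.0 and replicate 3 at 20.1, whereas Pvalb lies between 7255 and 8413 in all 3 MEF2C libraries.

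Markers of other cell types and of blood differed between the libraries beside these fibre genes. Haemoglobin and other blood genes were higher in the libraries labelled MEF2C, with a positive change in all 5 members and a median log2 difference of 0.61 (camera adjusted p = 0.00197; adjusted p = 0.676 with an estimated correlation). Hba-a2 stood at 4816 CPM in MEF2C replicate 1, 2443 in replicate 2 and 2738 in replicate 3, against 2080, 1738 and 2298 in GFP replicates 1, 2 and 3, and Hbb-bs had a log2 fold change of 0.66 ± 0.26 (edgeR adjusted p = 0.856). Granulocyte genes were abundant in MEF2C replicate 1. The neutrophil list of 9 genes summed to 1143 CPM there, to 72.9 in GFP replicate 3 and to between 2.66 and 5.73 in the other 4 libraries. Only S100a8 of that list was tested, with a log2 fold change of 3.79 ± 2.71 (edgeR adjusted p = 0.976).

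Higher lists also included smooth muscle and pericyte, tendon, adipocyte and extracellular matrix genes. In the smooth muscle and pericyte list 10 of 11 members were positive, 0 were called over all genes and 2 (Myh11 and Tagln) were higher adjusted over the list alone. Its median log2 difference was 0.21 (camera adjusted p = 0.0261). The tendon list had a positive change in all 7 members with a median of 0.47 (adjusted p = 0.0308), where Thbs4 stood at 224 ± 50.7 against 154 ± 31.9 CPM (SD, n = 3 per group). The adipocyte list had a positive change in 7 of 8 members with a median of 0.54 (adjusted p = 0.0385). Adipoq, the fat hormone adiponectin, stood at 35.8, 91.4 and 47.2 CPM in MEF2C replicates 1, 2 and 3 and at 24.0, 36.1 and 30.7 in GFP replicates 1, 2 and 3. In the extracellular matrix list 14 of 20 members were positive with a median of 0.15 (adjusted p = 0.0423), and Timp1 and Bgn had log2 fold changes of 1.12 ± 0.33 and 0.76 ± 0.25 (edgeR adjusted p = 0.641 and 0.749). No member of the tendon, adipocyte or matrix list was called, over all genes or adjusted over the list alone, and these 4 lists had an adjusted p = 0.676 with an estimated correlation. With library totals alone the tendon, adipocyte and matrix calls were lost, each with an adjusted p of 0.103, while the medians were larger, at 0.60 for tendon, 0.66 for adipocyte, 0.33 for smooth muscle and 0.27 for matrix genes. After the correction on transcript length the medians were 0.11 for smooth muscle and 0.04 for matrix genes, and the matrix call was lost (camera adjusted p = 0.132). The tendon and adipocyte medians were 0.47 and 0.54 after it.

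Lower lists besides the fast-fibre genes were excitation-contraction coupling, heat shock, class I antigen presentation, glycolysis, Schwann cell, proteasome and ribosomal protein genes. Members of the coupling list, which link the membrane signal to calcium release, were negative in 15 of 16 cases with a median of -0.24 (camera adjusted p = 0.00197), with Cacnb1 at -0.59 ± 0.17 and Jsrp1 at -0.51 ± 0.16. All 11 heat shock genes were negative, with a median of -0.29 (adjusted p = 0.0107), Hspa8 at -0.41 ± 0.16 and Bag3 at -0.31 ± 0.15. Class I antigen presentation genes were negative in 9 of 10 members with a median of -0.25 (adjusted p = 0.0107), with H2-K1 at -0.60 ± 0.21 and H2-Q7 at -0.65 ± 0.29. Glycolysis and glycogen genes were negative in 15 of 20 members with a median of -0.14 (adjusted p = 0.0423), where Gpd1 and Pkm stood at -0.41 ± 0.13 and -0.35 ± 0.12. Schwann cell markers were negative in 6 of 7 members with a median of -0.34 (adjusted p = 0.0385), with Prx at -0.78 ± 0.34 and Mbp at -0.35 ± 0.19. The proteasome and cytosolic ribosomal protein lists had medians of -0.05 and -0.07 (adjusted p = 0.0423 and 0.0107), and these medians turned to 0.08 and 0.06 with library totals alone, where the median of all genes moved from 0.01 to 0.14. With library totals alone the medians were also -0.12 for coupling, -0.17 for heat shock, -0.12 for class I, -0.22 for Schwann cell and -0.01 for glycolysis genes, and the glycolysis, proteasome and ribosomal calls were lost (adjusted p = 0.103, 0.365 and 0.277). The glycolysis (0.0611), Schwann cell (0.0571) and proteasome calls (0.114) were lost after the correction on transcript length, and the glycolysis call after that on GC content (0.0650). Their medians moved little: after the length correction they were -0.15, -0.35 and -0.04, and the glycolysis median was -0.13 after the GC correction. No member of these 7 lists was called over all genes or adjusted over the list alone. With an estimated correlation the adjusted p was 0.742 for glycolysis and the proteasome, 0.855 for ribosomal proteins and 0.676 for the other 4 lists.

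**Figure D3:**
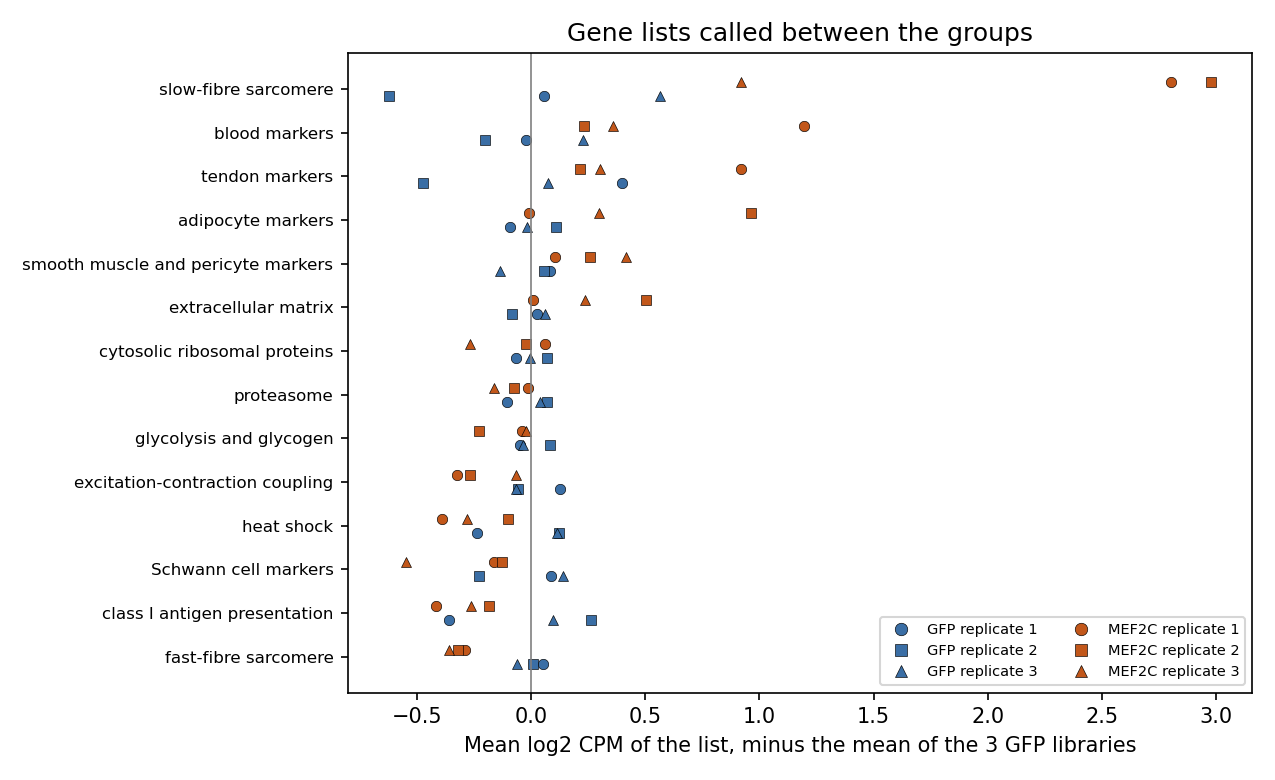
Mean log2 CPM of the tested members of each of the 14 called gene lists in each library, minus the mean of the 3 GFP libraries (x axis), in libraries labelled GFP (blue) and MEF2C (orange), with the replicate as the symbol. The slow-fibre list stands apart in MEF2C replicates 1 and 2, and the fast-fibre list is below the GFP libraries in all 3 MEF2C libraries.

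The slow-fibre, fast-fibre, excitation-contraction coupling and blood lists were called whichever library was left out, and each of the other 10 lost its call without at least 1. Without MEF2C replicate 1 the class I (adjusted p = 0.0546) and tendon lists (0.504) were lost. Without MEF2C replicate 2 the proteasome (0.0749), glycolysis (0.367), adipocyte (0.367) and matrix lists (0.519) were lost. Without MEF2C replicate 3 all of the 10 except class I were lost, with an adjusted p between 0.0556 and 0.806, and the ribosomal list turned upward. Without GFP replicate 1 the Schwann cell (0.0759), matrix (0.103) and adipocyte lists (0.152) were lost. Without GFP replicate 2 the heat shock, class I, glycolysis, matrix, tendon, proteasome and ribosomal lists were lost (0.213 to 0.409), and without GFP replicate 3 all of the 10 except the ribosomal list (0.0536 to 0.211). The count of 14 called lists became 6 without MEF2C replicate 3, 7 without GFP replicate 2 and 7 without GFP replicate 3. With no low-count filter the smooth muscle (0.0595), tendon (0.0948) and matrix lists (0.117) were lost, and with the strict filter the Schwann cell list (0.124). Of the 36 lists tested, 0 were called with an estimated correlation, where 1 had an unadjusted p under 0.05, and 0 were called by fry, where 3 had.

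The remaining 22 tested lists were not called, among them the MEF2-dependent muscle genes, with 8 of 19 members positive, a median log2 difference of -0.03 and a camera adjusted p of 0.356. In that list Klhl31, a Kelch protein of the sarcomere, stood at -0.56 ± 0.13 and was lower adjusted over the list alone (edgeR adjusted p = 0.274 over all genes), and Nr4a1 stood at -0.38 ± 0.16. The MEF2 family and its regulators had an adjusted p of 0.701, Z-disc genes 0.652, with 2 higher and 3 lower adjusted over the list alone, and developmental muscle genes 0.402, with the perinatal myosin Myh8 at 4.82 ± 1.06 against 1.18 ± 0.369 CPM (SD, n = 3 per group), higher adjusted over the list alone. In the denervation and neuromuscular junction list (adjusted p = 0.957) Chrna1 was the only member called by edgeR, over all genes and adjusted over the list alone. Metabolic lists gave an adjusted p of 0.156 for the respiratory chain, 0.899 for mitochondrially encoded proteins, 0.361 for the tricarboxylic acid cycle and 0.163 for fatty acid use. Atrophy and autophagy gave 0.956, growth signalling 0.957 and mechanosensing and nuclear envelope genes 0.701. The p53 and DNA damage list gave 0.0526, with Cdkn1a at 0.99 ± 0.24 (edgeR adjusted p = 0.443) and higher adjusted over the list alone, the unfolded protein response 0.899, immediate early genes 0.111, the interferon response 0.524 and class II antigen presentation 0.152. The circadian clock gave 0.508. Among cell markers, macrophages gave 0.705, endothelium 0.899, fibro-adipogenic progenitors 0.679 and satellite cells 0.361. The T and NK cell, B and plasma cell, neutrophil, cell cycle and sex-linked lists had 1, 0, 1, 4 and 4 tested members and were not tested as lists. With no low-count filter 40 lists had enough members, and T and NK cell markers were called lower and cell cycle genes higher (camera adjusted p = 0.0290 for each), with medians of -0.30 and 0.40, while the neutrophil (0.139) and B and plasma cell lists (0.716) were not called. Cell cycle counts were low and uneven between libraries. Top2a had 28, 4 and 6 counts in MEF2C replicates 1, 2 and 3 and 3, 4 and 12 in GFP replicates 1, 2 and 3. Mcm2 had 10, 16 and 8 against 15, 8 and 7, both genes chosen after their values were seen. Some of the 22 lists not called in the main test passed without 1 library: p53 without MEF2C replicate 2 (camera adjusted p = 0.04998) or GFP replicate 1 (0.0204), immediate early genes without MEF2C replicate 1 (0.0168) or GFP replicate 3 (0.0377), fatty acid use without MEF2C replicate 3 (0.000161), macrophages without GFP replicate 3 (0.0377), and the respiratory chain (0.0164), the interferon response (0.0129) and class II (1.38e-05) without GFP replicate 1. The p53 list also passed with DESeq2 size factors (0.0493) and the developmental list with the strict filter (0.0391). The median and the mean of the log2 differences had opposite signs for the MEF2 family, Z-disc, mitochondrially encoded, atrophy, growth, denervation, unfolded protein response and endothelial lists.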

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

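The corrections on length and GC content, the totals behind the deposited CPM and MEF2C replicate 3 alone were chosen after seeing the data. The count of 7 changed genes was 7 with DESeq2 size factors, 6 with library totals alone or limma-voom, and 7 with the length correction, the GC correction or the totals behind the deposited CPM. It was 35 with no filter, 28 with the DESeq2 Wald test, 4 without the 50 most abundant genes in the library size, 3 with the strict filter, 3 with the fold minimum and 0 with non-robust dispersion, where the smallest adjusted p was 0.078 and 557 genes had an unadjusted p under 0.05; the cause was not tested. Leaving out 1 library gave 0 to 22 genes, and MEF2C replicate 3 alone, with the lone library assumed to vary like the GFP libraries, gave 8, of which 0 were among the 7; with 1 library in that arm this says little about the 7. The split of calls was 3 higher and 4 lower, but 4 and 2 with library totals alone, 20 and 15 with no filter, 15 and 13 with DESeq2, 1 and 3 without the 50 most abundant genes, 1 and 2 with the strict filter and 2 and 4 with limma-voom. Over all alternatives the called genes kept direction and call in 74 cases and lost the call in 59, and the called lists in 167 and 84. Tested lists that were not called gained a call in 18 cases and were again not called in 378, whatever their direction. No called gene changed direction in its 19 settings; Chrna1 kept its call in 14, Pvalb in 13, Mylpf in 12, Ccl21a, Cyp2e1 and Rtn4 in 9 each and Myl1 in 8. The Mef2c difference was not past the test in any setting. Its log2 value lay between -0.16 and 0.33 when 1 library was left out, turning negative without MEF2C replicate 3. The 14 called lists became 8 with library totals alone and 0 with an estimated correlation or with fry; leaving out 1 library gave 6 to 15. The ribosomal list's adjusted p ran from 3.90e-06 to 0.806 when 1 library was left out, turning upward at 0.806 without MEF2C replicate 3. Among genes that were not called, Myh1 ran from -0.29 to 0.13 when 1 library was left out, turning positive without MEF2C replicate 3 (0.13) or GFP replicate 1 (0.02), and Myh2 and Lep turned to -0.85 and -0.31 with MEF2C replicate 3 alone; the cause was not tested. With the replicate number as a block, 2 genes (Chrna1 and Sln) and 15 lists were called. The numbers do not pair the samples: deviations from the group means correlated at -0.23, 0.05 and -0.25 for same-numbered libraries, and no library correlated best with its own number. Depth limits genes near 20 counts, such as Prr14, and in simulated data 6.87% of 1.5-fold changes were recovered.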

Other observations

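Of the tests below, those on a slower muscle, on viral transcripts, on adipose tissue and on transcript length in the split of libraries were chosen after the result was seen, as were the genes named only here. The tests on lymphatic markers, on wrong labels and the other tests on length and GC content also addressed patterns already seen in these data. Beside the neutrophil list, MEF2C replicate 1 held other genes of blood-forming cells. Elane and Mpo, a protease and a peroxidase of granulocyte precursors, had 201 and 129 counts there, 9 and 6 in GFP replicate 3 and at most 2 in each of the other 4 libraries, and the B cell gene Cd79a had 31 counts against at most 6 elsewhere. Bglap and Acp5, both highest in MEF2C replicates 1 and 2, were called by edgeR with MEF2C replicate 3 left out (adjusted p = 0.0189 and 0.0255), as were the slow-fibre genes Tnnt1, Tnni1, Tpm3, Atp2a2 and Casq2.

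The 3 against 3 design has 10 splits, too few for a share under 0.05. The real grouping called 7 genes and the highest of the other splits called 29, so that 2 of the 10 splits called as many. For gene lists the real grouping called 14, the highest other split 12, and 1 of the 10 splits, the real one, called as many.

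The split with 29 genes set MEF2C replicates 2 and 3 and GFP replicate 1 against the other 3 libraries, crossing the groups. It was picked for its count, and whether the samples have a structure that the labels do not give was not tested. Of its 29 genes, 28 were lower in MEF2C replicate 1 and GFP replicates 2 and 3, with Dnlz, Rbm38 and Slc25a1 at log2 differences of -1.57, -1.25 and -1.81, and 0 were among the 7 genes called between the groups. After a correction on transcript GC content the split called 25 genes, and after one on transcript length 28, so that neither trend alone removed most of the calls and what sets these libraries apart stays open. Both corrections left 7 genes called between the groups. Transcript length did differ between libraries: across genes, which are not independent replicates, levels correlated with length at a rho of 0.25 in MEF2C replicate 3 and 0.22 in GFP replicate 1, and at -0.17 to -0.05 in the other 4.

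For the fibre-type genes, a smooth trend with transcript length or GC content is argued against as the whole cause. Across tested genes the group log2 fold changes correlated at a rho of 0.05 with length and -0.05 with GC content. So weak a trend left the corrections little to remove. The slow list kept a median fitted log2 fold change of 2.37 ± 0.922 after the length correction and 2.37 ± 0.934 after the GC correction. These SEs came from a bootstrap over genes, which are not independent. The 3 called fast genes, selected by the same test, kept medians of -0.82 and -0.80, with median edgeR SEs per gene of 0.110 and 0.129. The whole fast list kept median differences in mean log2 CPM of -0.34 and -0.33. A candidate explanation is that the tissue labelled MEF2C held more of a slower muscle, the muscle not being named, which would give the excesses of all slow genes 1 ratio between libraries. Between MEF2C replicate 3 and replicates 1 and 2, where the median ratio over the 12 tested slow genes was 0.115, 2 of the 12 departed from it by more than 2 SD of the GFP libraries and 4 had no excess in replicate 3, while 8 of the 12 departed between replicates 1 and 2. That SD was taken where these genes were lower, so it does not measure their spread at the level of replicates 1 and 2. Between these 2 replicates Myl3 departed by 8.53 SD at a ratio of 1.16, against a median ratio of 0.879. The counts of departing genes therefore do not decide on 1 common ratio. The fall of the fast list in replicate 3 was 0.959 of that in replicates 1 and 2, above the slow genes' ratio (95% bootstrap interval over genes of the difference 0.237 to 1.94). The fast ratio was taken on log2 CPM and the slow ratio on CPM, so the difference sets unlike scales against each other. It also rests on 1 library, and between replicates 1 and 2 the interval ran from -0.498 to 0.600. A slower muscle therefore stays open for both gene groups. An action of MEF2C, which the design names, was not tested and stays open as well, with the slow genes lowest in replicate 3, where Mef2c stood at 371 CPM, and higher in replicates 1 and 2, where it was 0.895 times the GFP mean.

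The Mef2c level raises the question of what MEF2C replicates 1 and 2 received. Wrong labels on both cannot be told apart from correct ones: log2 fold changes of replicates 1 and 2 and of replicate 3, taken against different GFP libraries, correlated across genes, which are not independent replicates, at between -0.0591 and 0.126, and at between -0.203 and 0.192 with the GFP libraries divided the other way, so that the sign turned on which GFP library was used. The mean log2 CPM of the fast list ran with the labels, at 12.29 and 12.26 in replicates 1 and 2 against 12.58 ± 0.06 (SD, n = 3) in the GFP libraries. This list was called between the same labelled groups, so its separation by label does not check the labels. Distances between libraries sorted by label only in part. The chi-square per degree of freedom was 10.4 to 18.0 between these replicates and GFP libraries. That was above the 8.07 between replicates 1 and 2 and the 5.65 to 8.40 among the GFP libraries. Between replicate 1 and MEF2C replicate 3 it was 11.7, below the 12.2 to 18.0 between replicate 1 and the GFP libraries. Between replicate 2 and MEF2C replicate 3 it was 10.6, within the 10.4 to 16.5 between replicate 2 and the GFP libraries. Between MEF2C replicate 3 and GFP replicate 1 it was 7.88. Viral MEF2C transcripts that were not counted under Mef2c may equally be the case, since the ratio of 0.895 to the GFP mean is what either would give and the handling of viral sequence is not given in the sources used here. The excess in replicate 3 may in part be length or GC content: Mef2c has a transcript of 6277 bases, and the log2 gap of replicate 3 to the highest other library was 0.51 before and 0.12 after the length correction, within the SD of 0.22 among the other 5 libraries, and 0.24 after the GC correction.

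The levels of Ccl21a and Cyp2e1 were set against markers of cells known to express them. A higher share of lymphatic endothelial cells stays open for Ccl21a: 5 other lymphatic markers had a median fitted log2 fold change of 0.22 ± 0.32 (bootstrap SE) against 0.69, which is 0.5 times that of Ccl21a, with Lyve1 at 0.77 ± 0.24 and Flt4 at -0.01 ± 0.40. More adipose tissue in the samples labelled MEF2C stays open for Cyp2e1, since the answer turned on the measure: 8 adipocyte markers had a median fitted log2 fold change of 0.70 ± 0.22 against 0.58, which is 0.5 times that of Cyp2e1, but a median difference in mean log2 CPM of 0.54 against 0.57, and the adipocyte list lost its call without MEF2C replicate 2 (adjusted p = 0.367), MEF2C replicate 3 (0.0556), GFP replicate 1 (0.152) or GFP replicate 3 (0.0969).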
